A study of Mus musculus with 8 samples.

How the data were processed

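Whole esophagi of 8 male mice were sequenced as polyA-selected RNA in paired-end mode on an Illumina HiSeq instrument, per the labels' protocols. The EoE33 and wild type groups held 4 mice each, taken from the sample titles. The authors deposited raw counts per gene in 1 table of 49315 Ensembl gene identifiers and 8 columns. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 and the genome build GRCm38 are named in the submitters' processing notes, without their roles. The annotation release, the use of strand and the treatment of reads that match several places are not given in the sources used here. If strand was not used, reads of overlapping and antisense genes cannot be told apart. Column names of the deposited counts do not name the mice: each sample's description gives a spreadsheet column letter, and columns were assigned to samples by that letter. All 8 columns were used.

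Of the identifiers, 48970 matched GENCODE M21 (GRCm38), which gave symbols and coordinates, and 345 did not. Library depth lay between 17.73 and 24.07 in units of 1e6 counts. No pair of libraries agreed within sampling noise: chi-square per degree of freedom within groups lay between 10.38 and 70.1, over genes with at least 10 counts in the pair.

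Genes were filtered with edgeR's filterByExpr by group, which left 16760, and scaled by TMM factors. Differences were tested with edgeR 4.0.16 (glmQLFit with robust = TRUE and glmQLFTest) in R 4.3.3, with genotype as the model term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Levels are CPM, counts per 1e6 counts computed from the deposited counts with TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Their median was 0.368 for genes with a mean under 1 CPM, 0.221 from 1 to 10 CPM, 0.096 from 10 to 100 CPM and 0.089 above. A gene with 0 counts in a group was compared with a floor of 3 counts over the group, and genes with 1 to 3 counts got an exact 95% interval of the count ratio. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. In single libraries the floor corresponded to 0.127 to 0.176 CPM.

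The 32 gene lists and the rule for named genes were written before the data were examined. The rule took Il33, the 15 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 4 members with the smallest p of each list, 17 genes of the disease, and the 5 smallest p-values. From the largest changes, 3 higher and 1 lower unnamed gene models or immunoglobulin segments were passed over. The rule named 153 genes, and the results of 3 of them are not reported here. Other genes named in the text are list members that went against their list, members whose number needed naming, or markers of other tissue, and were chosen after their values were seen. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over 30 lists. Symbols missing from the annotation were looked up through RefSeq synonyms, and Il36b is present as Il1f8. Il36a is present as Il1f6, but the lookup left it out because its RefSeq entry carries a further symbol of the annotation, and its list was run again with it afterwards.

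The procedure was tested on simulated counts for the same 16760 genes and the EoE33 against wild type design. Of 50 genes each, it recovered 46% at 1.5-fold, 72% at 2-fold, 94% at 4-fold and 100% at 0.25-fold, with 7 false calls, 3.8% of all 184 calls. The other 21 calls were of 30 further genes raised 2-fold as a list. A raised list gave a camera p of 9.42e-89 and an unchanged list 0.802. Genes were simulated independently, so these 2 values do not cover lists of correlated genes. Only a small part of the genes was changed, all above 1 CPM in wild type. The false call share therefore does not carry over to data where 63.4% of genes were called.

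Alternatives were DESeq2 size factors, upper-quartile scaling, library size only, DESeq2 1.42.0, limma-voom, a fit with robust = FALSE, other low-count filters, the replicate number or the skeletal muscle level as a further term, the first surrogate variable of sva 3.50.0, stricter thresholds, and leaving out each library in turn. Chosen after seeing the data were library size without the counts of Chil4, leaving out wild type replicates 1 and 3, and adding Il36a to its list. Genotype is the only grouping in the labels used, and no batch is given there. Antibody, histology or protein data were not analysed here.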

Results

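RNA of whole esophagus was measured in 8 male mice aged 8 weeks. The EoE33 group held 4 mice that carry a transgene for overexpression of IL-33 in the esophagus. The control group held 4 wild type littermates of the C57BL/6J strain. IL-33 is an alarmin cytokine released by epithelial cells, and its receptor ST2 is encoded by Il1rl1. The series concerns eosinophilic esophagitis, a chronic inflammation of the esophagus rich in eosinophils, and its dependence on IL-13. The comparison asks which transcripts differ in the esophagus when IL-33 is overexpressed. Library depth, in units of 1e6 counts, lay between 17.73 and 24.07, with a mean of 23.2 ± 0.81 in wild type and 20.43 ± 1.93 in EoE33 (SD, n = 4 each). Mitochondrial transcripts took 3.01% ± 0.18 of the counts in wild type and 1.9% ± 0.21 in EoE33 (SD, n = 4 each). Chil4 alone took 8.21% ± 1.89 of the counts in EoE33 and 0.018% ± 0.002 in wild type (SD, n = 4 each).

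Il33 itself was higher in all 4 EoE33 libraries than in any wild type library. The gene (ENSMUSG00000024810) lies on chromosome 19 from 29925114 to 29960718 in GRCm38. Its level was 128.9 ± 27.1 CPM in wild type and 371.3 ± 16.1 CPM in EoE33 (SD, n = 4 each), a 2.88-fold rise. The log2 fold change was 1.53 with a standard error of 0.14 (edgeR adjusted p = 1.52e-05). A two-sided exact permutation test of log2 CPM gave p = 0.0286, the smallest that the 70 orderings of 4 against 4 can give. Counts per gene do not separate transgene transcripts from those of the endogenous gene.

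Across the transcriptome, 5238 genes were higher and 5383 lower in EoE33, together 63.4% of the 16760 genes tested (edgeR quasi-likelihood test). With an absolute log2 fold change of at least 1, 2057 were higher and 2496 lower. All EoE33 libraries lay above all wild type libraries in 4963 genes and below them in 5003, 59.5% of tested genes, where chance gives 2.86%. The first principal component held 81.6% of the variance and separated the groups, and the second held 5.5%. Libraries stood apart within wild type: replicate 3 held airway transcripts (Scgb1a1 at 350.6 CPM against 5.44 to 5.9 in the other 3) and replicate 1 held liver transcripts (Alb at 91.3 CPM against 3.21 to 6.9). Without those 2 libraries, an alternative chosen after seeing the data, 4332 genes were higher and 4495 lower.

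**Figure D1:**
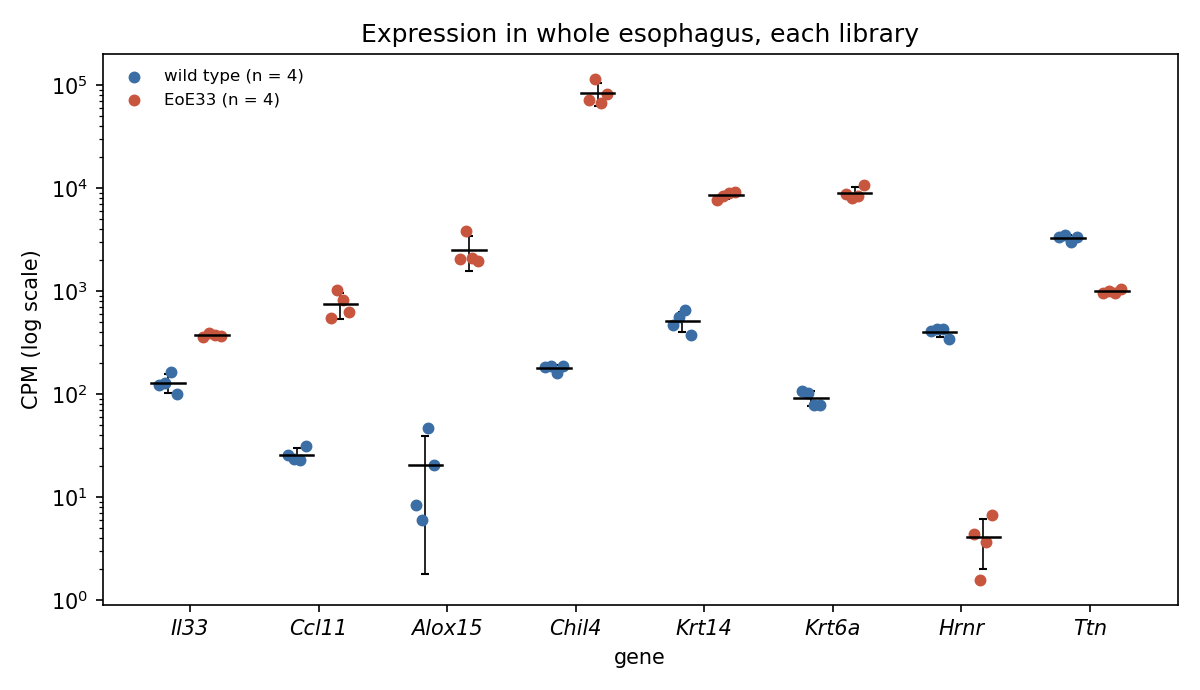
CPM (log axis) of 8 genes in each of the 4 wild type and 4 EoE33 libraries; dots are libraries, horizontal bars the group mean and error bars 1 SD. Il33, Ccl11, Alox15, Chil4, Krt14 and Krt6a lay higher in every EoE33 library, and Hrnr and Ttn lay lower, with Chil4 at a mean of 83220 CPM in EoE33 and 179.4 CPM in wild type.

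Among the largest rises were those of a transporter gene, a chitinase-like gene and 2 chemokine genes. Slc26a4, which encodes the anion exchanger pendrin, rose from 0.15 ± 0.11 to 89.2 ± 39.4 CPM (SD, n = 4 each; 572-fold, log2 fold change 9.16, standard error 0.57). Chil4, a chitinase-like protein gene on chromosome 3 from 106201490 to 106219507 (GRCm38), rose from 179.4 ± 13.4 to 83220 ± 21300 CPM (SD, n = 4 each). Its fold was 464 and its edgeR adjusted p 6.58e-08. The neutrophil chemoattractants Cxcl5 and Cxcl3 rose 532-fold and 311-fold. The small proline-rich genes Sprr2e, Sprr2f and Sprr2d rose 507-fold, 406-fold and 383-fold. Gsdmc2, a gasdermin gene, rose 309-fold, and Il19, a cytokine gene of the IL-10 family, rose 333-fold. Pla2g4c, a phospholipase A2 gene, rose 322-fold. Rnase2a, an eosinophil-associated ribonuclease gene, rose 344-fold, from 7 counts over the wild type libraries to 2196 over the EoE33 libraries. Its log2 fold change of 8.43 was 9.15 without wild type replicate 3. Tgm6, Stfa2l1 and Mcpt2 had 0 counts in all wild type libraries. Against a floor of 3 counts over the group they were at least 145-fold, 94.6-fold and 86.2-fold higher in EoE33. Mmp10 had 1 count in wild type and 866 in EoE33, a count ratio of 995 with a 95% interval from 178 to 39340. Its log2 fold change of 9.44 was 10.95 without wild type replicate 4 and 8.41 without EoE33 replicate 2. The smallest p-values belonged to B3galt5, Elf3, Aldh1a3, Ceacam1 and Urah, which rose 256-fold, 33.2-fold, 117-fold, 103-fold and 18.9-fold.

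Among the largest falls were genes of the cornified layer of squamous epithelium. Flg, which encodes profilaggrin, lies on chromosome 3 from 93273523 to 93293686 (GRCm38) and fell from 146.3 ± 89.9 to 0.93 ± 0.63 CPM (SD, n = 4 each; log2 fold change −7.28, standard error 0.94, edgeR adjusted p = 0.000325). Hrnr, the hornerin gene, fell from 399.4 ± 41.1 to 4.07 ± 2.09 CPM (SD, n = 4 each). The protease gene Klk5 and the metallothionein gene Mt4 were 112-fold and 92.5-fold lower. Skint6 was 192-fold lower, and its log2 fold change of −7.59 was −9.12 without EoE33 replicate 3. Tmem45a2 was 178-fold lower. Slurp2 had a log2 fold change of −7.12, or −8 without EoE33 replicate 4. Serpinb13 had a log2 fold change of −6.64, or −7.48 without EoE33 replicate 3. Cyp2b19 had 248 counts in wild type and 1 in EoE33, a count ratio of 0.00463 with a 95% interval from 0.000117 to 0.0261. Its log2 fold change of −7.20 was −8.91 without EoE33 replicate 2. Scgb1a1, the secretoglobin of airway club cells, had a log2 fold change of −7.16 that was −3.15 without wild type replicate 3 and that did not pass without EoE33 replicate 2 (edgeR adjusted p = 0.0528).

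Gene lists were fixed before the data were examined, and 30 of 32 held at least 5 tested genes. By the camera test 14 lists were higher and 5 lower in EoE33, and all 19 calls were lost with an estimated correlation between genes, whose adjusted p is given with each list. Of the 35 splits of the 8 libraries into 4 and 4, 6 gave as many list calls, the real one included. Counts of members adjusted over the list alone were equal to those over all genes tested except where given.

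**Figure D2:**
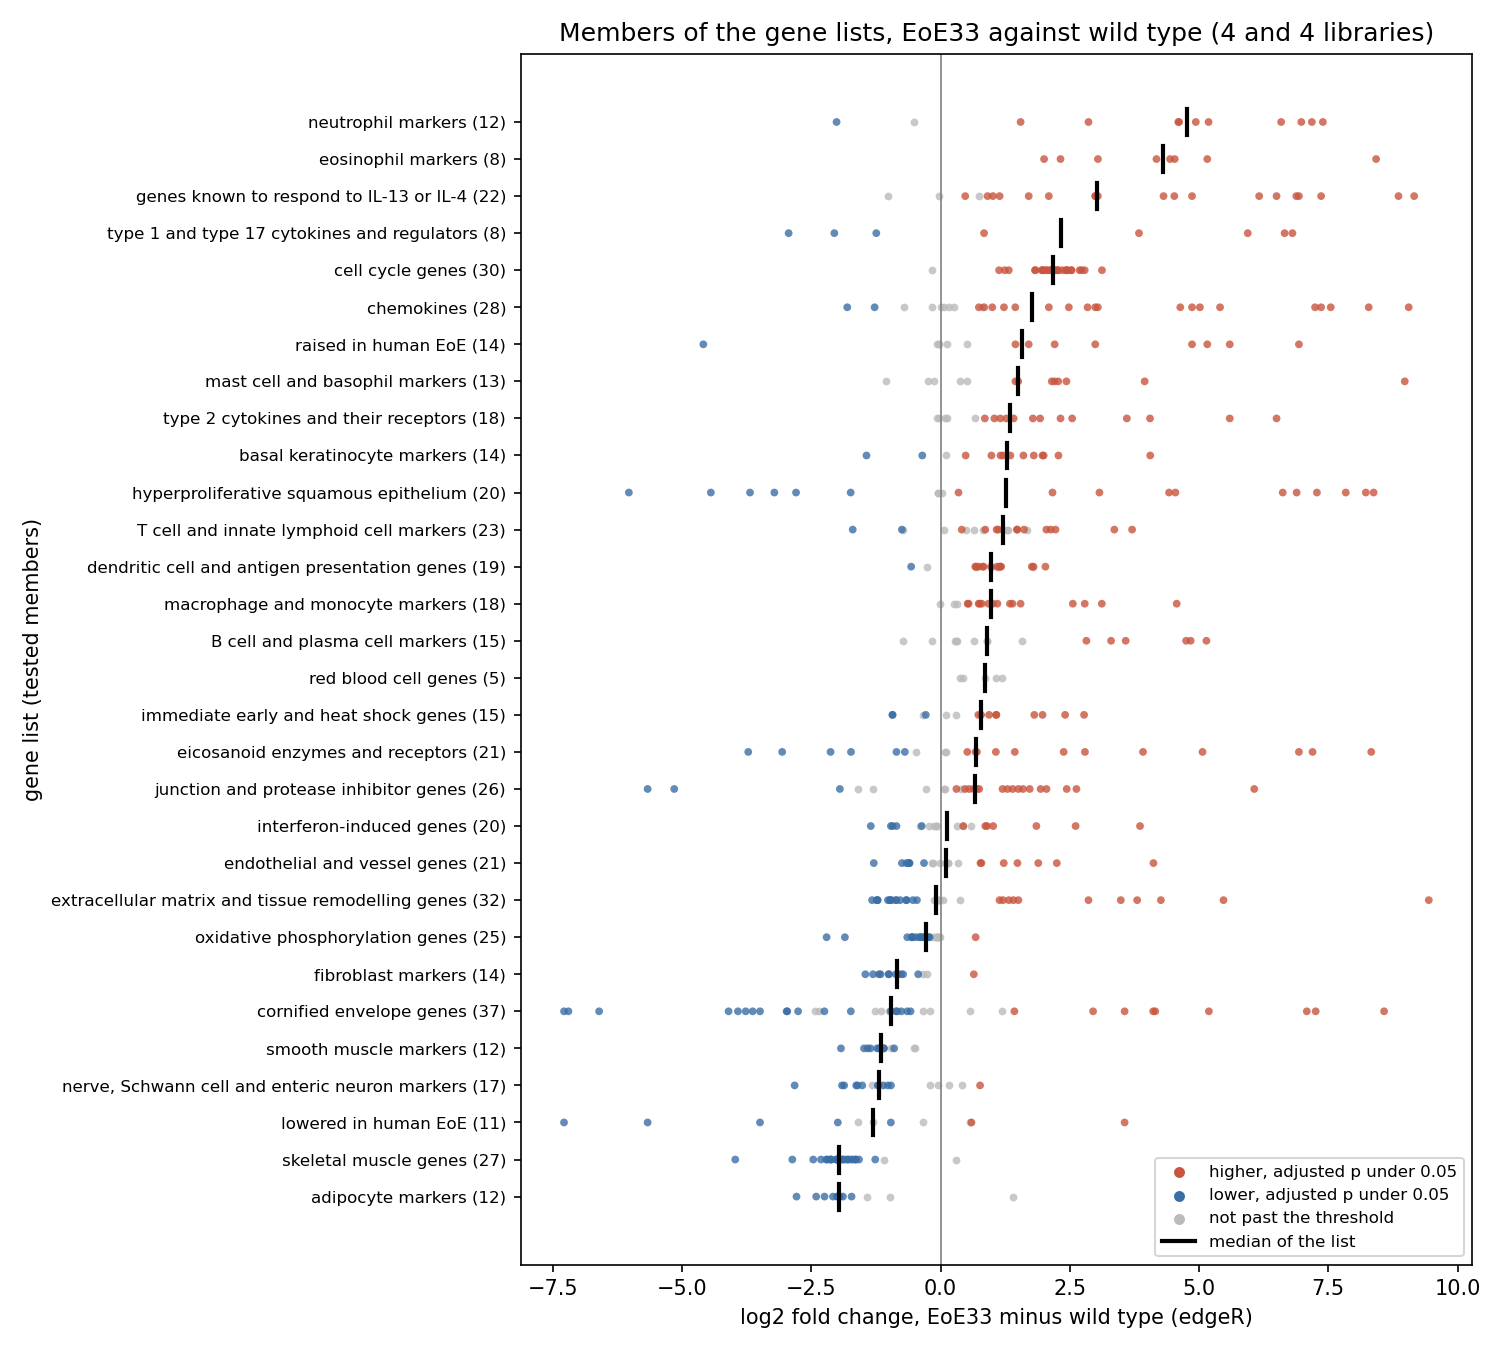
Log2 fold changes (EoE33 minus wild type, edgeR) of the tested members of 30 gene lists, 1 dot per gene, from 4 EoE33 and 4 wild type libraries; red and blue dots passed an adjusted p of 0.05, grey dots did not, and black bars are list medians. Neutrophil and eosinophil markers had the highest medians, 4.78 and 4.31, and skeletal muscle genes and adipocyte markers the lowest, −1.96 and −1.97.

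Of the type 2 cytokines and their receptors, 13 of 18 tested genes rose and 5 did not pass (camera adjusted p = 8.42e-05, adjusted p = 0.303 with an estimated correlation). Il13, the type 2 cytokine gene on chromosome 11 from 53631324 to 53634702 (GRCm38), had 4 counts over the wild type libraries and 193 over the EoE33 libraries. Its level was 0.044 ± 0.062 CPM in wild type and 2.34 ± 0.91 CPM in EoE33 (SD, n = 4 each; log2 fold change 5.59, standard error 0.63, edgeR adjusted p = 6.17e-05). The value was 6.89 without wild type replicate 2. Il4ra and Il13ra1, the chains of the receptor for IL-4 and IL-13, rose 16.6-fold and 2.66-fold. The IL-33 receptor genes Il1rl1 and Il1rap rose 3.45-fold and 2.06-fold, and Csf2rb, the shared receptor chain for IL-3, IL-5 and GM-CSF, rose 5.84-fold. For Il4 the log2 fold change was −0.06 with a 95% interval from −0.69 to 0.57, and for Il5 it was −0.03 with an interval from −0.65 to 0.59. For Tslp, the gene of another epithelial alarmin, it was 0.12 with an interval from −0.5 to 0.74. These 3 cytokines had between 69 and 105 counts per group, and their signs turned under other settings.

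Genes known to respond to IL-13 or IL-4 rose in 19 of 22 tested members, or 20 adjusted over the list alone (median log2 fold change 3.02, camera adjusted p = 1.78e-11, adjusted p = 0.0911 with an estimated correlation). Ccl11, which encodes the eosinophil chemoattractant eotaxin-1, rose from 25.8 ± 3.94 to 752.1 ± 213 CPM (SD, n = 4 each; 29.1-fold). Arg1, the arginase of alternatively activated macrophages, rose 19.9-fold and Socs1, an inhibitor of cytokine signalling, rose 7.97-fold. Alox15, a 15-lipoxygenase gene, rose from 20.3 ± 18.6 to 2484 ± 910 CPM (SD, n = 4 each), and its log2 fold change of 6.93 was 7.74 without wild type replicate 3. Ccl24, the eotaxin-2 gene, had a log2 fold change of 2.99, or 2.12 without EoE33 replicate 2. Postn, the periostin gene, did not pass, with 294.8 ± 46.1 CPM in wild type and 287.9 ± 46.8 CPM in EoE33 (SD, n = 4 each) and a log2 fold change of −0.03 (95% interval −0.37 to 0.3).

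All 8 tested eosinophil markers rose (median log2 fold change 4.31, camera adjusted p = 3.87e-07, adjusted p = 0.0911 with an estimated correlation). Siglecf, a surface lectin gene, rose 18.1-fold and Ccr3, the receptor gene for the eotaxins, rose 35.7-fold. Rnase2b and Ear2, eosinophil-associated ribonuclease genes, rose 23.1-fold and 8.25-fold. Of the 150-base windows of their longest transcripts, 0% for Rnase2a, 0% for Rnase2b and 6.32% for Ear2 occur in transcripts of another gene, for Ear2 in Ear10. Mean levels in EoE33 were 27.8 CPM for Rnase2a and 166.8 CPM for Rnase2b, against 2.8 CPM for Siglecf. Bulk libraries do not show whether eosinophils alone made the ribonuclease transcripts. Prg2, the major basic protein gene, had a log2 fold change of 4.44, which was 5.46 without wild type replicate 3 and 3.79 without EoE33 replicate 3. Its mean was 0.064 CPM in wild type and 1.5 CPM in EoE33. Epx, the eosinophil peroxidase gene, had 3 counts over the wild type libraries and 19 over the EoE33 libraries and was not tested. Prg3, Ear1 and Ear6 of the same list also had too few counts to test. Of the mast cell and basophil markers, 8 of 13 rose and the list did not pass (camera adjusted p = 0.0821). It passed without wild type replicate 1 (camera adjusted p = 0.0486), wild type replicate 4 (0.00686) or EoE33 replicate 1 (0.0383). Hdc, which makes histamine, rose 15.4-fold, the chymase gene Cma1 5.4-fold and the IgE receptor gene Ms4a2 4.62-fold. Cpa3, the mast cell carboxypeptidase gene, passed narrowly with a log2 fold change of 1.45 (edgeR adjusted p = 0.0414). Without wild type replicate 1, 2 or 3 its adjusted p was 0.0722, 0.0666 and 0.0895. Without EoE33 replicate 1, 3 or 4 it was 0.0661, 0.0943 and 0.08.

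Lymphocyte markers gave no list call by camera with all 8 libraries. The fry test, which asks another question, called the T cell list (fry adjusted p = 0.00932) and the B cell list (0.048). Of the T cell and innate lymphoid cell markers, 12 of 23 rose and 2 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0731, or 0.00102 and a call without wild type replicate 4). Klrg1 and Icos, present on activated lymphocytes and innate lymphoid cells, rose 13-fold and 10.3-fold, while Rora and Thy1 were 3.25-fold and 1.68-fold lower. In wild type, Rora and Thy1 were at 113.1 and 30.98 CPM, and the highest other tested member was Cd5 at 14.65 CPM. Bulk libraries do not assign the falls of Rora and Thy1 to lymphocytes. Of the B cell and plasma cell markers, 6 of 15 rose (camera adjusted p = 0.111, or 0.0379 and a call without wild type replicate 3). The plasma cell genes Tnfrsf17 and Mzb1 rose 12-fold and 7.07-fold. Jchain and Ighm had log2 fold changes of 5.14 and 4.75, or 6.24 and 5.65 without wild type replicate 3.

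Myeloid markers rose as lists. Macrophage and monocyte markers rose in 15 of 18 members (camera adjusted p = 0.00013, adjusted p = 0.434 with an estimated correlation), with Trem2, Ms4a7, Cd14 and Cd68 5.89-fold, 6.91-fold, 8.69-fold and 2.92-fold higher. Dendritic cell and antigen presentation genes rose in 13 of 19 members, or 15 adjusted over the list alone, and fell in 1 (camera adjusted p = 0.011, adjusted p = 0.556 with an estimated correlation). The MHC class II genes H2-Aa and H2-Ab1 rose 2.25-fold and 2.22-fold, and the integrin gene Itgax 3.47-fold. Zbtb46, a transcription factor gene of conventional dendritic cells, was the member that fell, with a log2 fold change of −0.57. H2-DMa rose 1.76-fold, but it overlaps Brd2, at 191.8 CPM. Neutrophil markers rose in 10 of 12 members (median log2 fold change 4.78, camera adjusted p = 0.00197, adjusted p = 0.329 with an estimated correlation). The calprotectin genes S100a8 and S100a9, which keratinocytes also express, rose 168-fold and 30.6-fold. Retnlg had a log2 fold change of 6.98, or 7.88 without wild type replicate 4. Il1r2, a decoy receptor for IL-1, was 4.04-fold lower, and Camp, an antimicrobial peptide gene, did not pass, with a log2 fold change of −0.51 (edgeR adjusted p = 0.336). In wild type Il1r2 was at 61.8 CPM, where Ly6g and Retnlg were at 0.011 and 0.3 CPM but Ltf at 46.3 CPM. Bulk libraries do not assign the fall of Il1r2 to neutrophils. Chemokines rose in 19 of 28 members and fell in 2, or 3 adjusted over the list alone (camera adjusted p = 1.15e-06, adjusted p = 0.303 with an estimated correlation). Ccl8, another ligand that attracts eosinophils and T cells, rose 164-fold. Ccl27a and Cxcl9 fell, with log2 fold changes of −1.28 and −1.80.

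Cytokines and regulators of type 1 and type 17 immunity were split, with 5 of 8 higher and 3 lower (camera adjusted p = 0.271). Il1b rose 101-fold, and Il23a had 3 counts in wild type and 190 in EoE33, a count ratio of 72.8 with a 95% interval from 24.5 to 356. Il12a was 4.16-fold lower, and Il18, a cytokine gene of epithelium and macrophages, had a log2 fold change of −2.94. Ifng and Il17a were among the 9 members with too few counts to test. Interferon-induced genes also moved both ways, with 7 of 20 higher and 5 lower (camera adjusted p = 0.443). Oasl1, Oas3 and Oas1a rose 14.5-fold, 6.11-fold and 3.61-fold, while Ifit2 was 2.55-fold lower.

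Cell cycle genes and basal keratinocyte markers rose, and bulk libraries do not assign the former to a cell type. Cell cycle genes rose in 29 of 30 members (median log2 fold change 2.18, camera adjusted p = 6.79e-26, adjusted p = 0.179 with an estimated correlation). Adjusted over the list alone, 29 rose and 1 fell. Mki67, a marker of cycling cells, rose from 46.6 ± 9.16 to 212.1 ± 44.6 CPM (SD, n = 4 each; 4.56-fold). The replication helicase gene Mcm5, the mitotic kinase gene Plk1 and the centromere genes Cenpe and Cenpa rose 8.71-fold, 5.49-fold, 5.37-fold and 4.39-fold. Basal keratinocyte markers rose in 11 of 14 members and fell in 2 (camera adjusted p = 5.45e-05, adjusted p = 0.329 with an estimated correlation). The keratin genes Krt14 and Krt5, which mark the basal layer, rose 16.6-fold and 3.92-fold. The integrin gene Itga6 rose 4.86-fold. Krt15 and Dst were the 2 that fell, with log2 fold changes of −1.43 and −0.35. Genes of hyperproliferative or wounded squamous epithelium rose in 11 of 20 members and fell in 6 (median log2 fold change 1.26, camera adjusted p = 0.00013, adjusted p = 0.121 with an estimated correlation). These counts leave out Il36a, which was missed in the lookup of symbols and had a log2 fold change of −1.65 that did not pass (edgeR adjusted p = 0.0953). With it, an alternative added after seeing the data, the median was 0.35 and the camera adjusted p 0.000324. Krt6a rose from 91.3 ± 15 to 8974 ± 1223 CPM (SD, n = 4 each; 98.3-fold), and Krt17 and Hbegf, a growth factor gene, rose 155-fold and 8.42-fold. Of the 150-base windows of the longest Krt6a transcript, 26.8% occur in transcripts of Krt6b or 2 unnamed gene models, so its counts may be shared with them. Those that fell were Serpinb3a, Serpinb3b, Serpinb3c, Defb4, Ereg and Il36b, which encode serine protease inhibitors, a defensin, a growth factor and a cytokine.

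Differentiation and cornified envelope genes moved in both directions. Of 37 tested members 9 rose and 19 fell, or 21 adjusted over the list alone. The list's median log2 fold change was −0.96 and its mean −0.54, while camera placed it in the upward direction without a call (camera adjusted p = 0.982). The genes Sprr2d, Sprr2a3 and Sprr2a1 rose 383-fold, 136-fold and 17.3-fold, and Hrnr was 97.4-fold lower. Sprr2a1 overlaps Sprr2a2, at 39.5 CPM. Of the 150-base windows of their longest transcripts, 89.6% for Sprr2a1 and 19% for Sprr2a3 occur in other Sprr2a genes, so the counts of these 2 are uncertain, against 0% for Sprr2d. Junction and protease inhibitor genes of the barrier rose in 17 of 26 members, or 18 adjusted over the list alone, and fell in 3 (camera adjusted p = 0.000328, adjusted p = 0.423 with an estimated correlation). The claudin genes Cldn4 and Cldn1 and the basal desmoglein gene Dsg3 rose 6.18-fold, 4.14-fold and 5.43-fold. The 3 that fell were the desmosomal cadherin genes Dsg1a and Dsc1, found in upper layers of stratified epithelium, and the protease inhibitor gene Cst6. Dsg1a fell from 364.5 ± 116 to 7.13 ± 4.7 CPM (SD, n = 4 each; log2 fold change −5.67).

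Muscle and connective tissue transcripts fell. Skeletal muscle genes, which in mice mark the muscle coat of the esophagus, fell in 25 of 27 members (median log2 fold change −1.96, camera adjusted p = 1.23e-18, adjusted p = 0.121 with an estimated correlation). Ttn, which encodes the sarcomere protein titin, fell from 3294 ± 206 to 993.7 ± 43 CPM (SD, n = 4 each; 3.32-fold lower). The calcium channel gene Cacna1s and the fast troponin genes Tnni2 and Tnnt3 were 3.59-fold, 4.04-fold and 3.73-fold lower. Smooth muscle markers fell in 9 of 12 members, or 10 adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.593 with an estimated correlation). Of these Des and Synm, which striated muscle also expresses, were 2.79-fold and 2.66-fold lower, and Lmod1 and Synpo2 were 3.8-fold and 2.56-fold lower. Fibroblast markers fell in 11 of 14 members and rose in 1 (camera adjusted p = 0.0028, adjusted p = 0.507 with an estimated correlation), with Fbln2, Dpt, Clec3b and Cd34 2.74-fold, 2.29-fold, 2.24-fold and 2.01-fold lower. The member that rose was the matrix gene Fbln1, with a log2 fold change of 0.64. Nerve, Schwann cell and enteric neuron markers fell in 11 of 17 members and rose in 1 (camera adjusted p = 0.0133, adjusted p = 0.329 with an estimated correlation). The member that rose was Mbp, a myelin gene, with a log2 fold change of 0.76. Nos1, expressed by inhibitory enteric neurons and by skeletal muscle, was 7.08-fold lower, Sox10 3.64-fold, Ncam1 3.05-fold and Ret 2.03-fold. Adipocyte markers fell in 9 of 12 members, or 10 adjusted over the list alone, without a list call (camera adjusted p = 0.0648). The list passed without wild type replicate 2 (camera adjusted p = 0.0363) or wild type replicate 3 (0.00432). Lep, Plin4 and Lpl were 4.23-fold, 4-fold and 3.86-fold lower. Plin1 had a log2 fold change of −2.41 and did not pass without wild type replicate 4 (edgeR adjusted p = 0.0577). Oxidative phosphorylation genes fell in 16 of 25 members and rose in 1 (median log2 fold change −0.29, camera adjusted p = 0.0107, adjusted p = 0.507 with an estimated correlation). The largest falls named were in Cox7a1 and Cox6a2, subunits found mainly in muscle, at 4.61-fold and 3.61-fold lower, against 1.46-fold for Ndufv2 and 1.39-fold for Ndufb8. Ndufa4, a cytochrome oxidase subunit gene, rose with a log2 fold change of 0.68. When the mean level of the skeletal muscle list was added to the model, 3 genes were higher and 0 lower at the edgeR threshold. That level differed between the groups without overlap, from 9.36 to 9.52 in wild type and from 7.26 to 7.81 in EoE33 (log2 CPM), so the model could hardly separate it from genotype.

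Matrix and vessel genes moved both ways. Of 32 extracellular matrix and remodelling genes 11 rose and 15 fell (median log2 fold change −0.09, mean 0.7, camera upward without a call, adjusted p = 0.982). The metalloproteinase genes Mmp12 and Mmp14 rose 19.2-fold and 2.84-fold and Tgfb1 2.2-fold, while Mmp2 was 1.94-fold lower. Of 21 endothelial and vessel genes 7 rose and 7 fell (camera adjusted p = 0.589). Sele and Icam1, adhesion molecules of activated endothelium, rose 17.4-fold and 3.71-fold, as did Pdpn, 2.8-fold, and Tek was 2.45-fold lower.

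Eicosanoid enzymes and receptors rose in 12 of 21 members and fell in 6 (camera adjusted p = 0.00544, adjusted p = 0.123 with an estimated correlation). Alox12e, a lipoxygenase gene, rose 147-fold, Hpgds, which makes prostaglandin D2, 15.1-fold and the leukotriene B4 receptor gene Ltb4r1 2.71-fold. Immediate early and heat shock genes rose in 9 of 15 members, or 10 adjusted over the list alone, and fell in 3 (camera adjusted p = 0.0229, adjusted p = 0.507 with an estimated correlation). Fos, Atf3 and Ier3 rose 6.85-fold, 3.51-fold and 2.11-fold, and Junb, which overlaps Prdx2, rose 3.93-fold. The 3 that fell were Jun and the heat shock genes Hspa1a and Hsph1.

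Genes known to be raised in human eosinophilic esophagitis rose in 8 of 14 tested mouse counterparts and fell in 1 (camera adjusted p = 0.00758, adjusted p = 0.303 with an estimated correlation). Those that rose were Alox15, Ano1, Cpa3, Ccl11, Ccl24, Ccr3, Il13 and Ms4a2. The chloride channel gene Ano1 rose 3.26-fold, and the sodium-proton exchanger gene Slc9a3 was the member that fell, with a log2 fold change of −4.59. Genes known to be lowered in the human disease fell in 5 of 11 counterparts and rose in 2 (camera adjusted p = 0.255). Flg, Dsg1a, Tgm3, Krt13 and Zbtb16 fell, Zbtb16 3.97-fold, whereas Crnn and Il1rn rose, Crnn 11.8-fold from 0.18 ± 0.12 to 2.23 ± 1.26 CPM (SD, n = 4 each).

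Markers of neighbouring tissue and blood were low or uneven. None of 5 red blood cell genes passed (camera adjusted p = 0.668), with log2 fold changes of 1.08 for Hbb-bt, 0.86 for Hbb-bs and 0.43 for Hba-a1. For Alas2 it was 1.19, and without EoE33 replicate 2 it was 1.52 and passed (edgeR adjusted p = 0.0302). Gkn3 was the 1 gastric marker with enough counts to test, of 13 symbols of which 2 name the same gene, and it was 4.85-fold lower, with 75 counts in wild type and 13 in EoE33. Of the airway and thyroid markers 4 of 13 were tested and 2 fell, or 1 adjusted over the list alone. Bpifa1, which encodes a secreted airway protein, had a log2 fold change of −7.02 (edgeR adjusted p = 0.0485), which was 0.51 without wild type replicate 3 and did not pass without any EoE33 replicate (adjusted p from 0.0934 to 0.112). Bpifb1 had a log2 fold change of −2.55 that did not pass (edgeR adjusted p = 0.236). Without wild type replicate 3 it was 3.45 and passed as a rise (edgeR adjusted p = 0.00139). Tshr, the thyrotropin receptor gene, had a log2 fold change of −1.03 that did not pass, or −1.41 without wild type replicate 3, where it passed (edgeR adjusted p = 0.0121). Without wild type replicate 4 the value for Tshr was −0.41 (edgeR adjusted p = 0.609).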

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

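The tests on dilution of other tissue, on the counts of Chil4 as a cause of the muscle change and on a mislabelled library were chosen after the values were seen. The tests on further muscle genes and on a second set of airway genes were written before those genes were looked at. Of 308 groups of 4 libraries tested by the gap of the outermost library relative to the range, 22 held a library far from the other 3, or 7.1%, where chance gives about 5%. Wild type replicates 3 and 4 were that library 5 times each, EoE33 replicate 2 4 times.

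Airway transcripts stood out in wild type replicate 3. The ratio of gap to range was 1 for Bpifa1 (635.5 CPM against 0.75 to 0.93), 0.999 for Scgb1a1 (350.6 against 5.44 to 5.9) and 0.995 for Bpifb1 (48.5 against 0.088 to 0.34). A mislabelled EoE33 library is argued against by its Chil4 level of 159.4 CPM, where the lowest EoE33 library had 66406 CPM. Airway tissue in the piece may be the source. In a second set of 29 airway genes, wild type replicate 3 was the highest of the 4 wild type libraries for 25, where chance gives 1 in 4. These were all 9 secretory and all 14 ciliated cell genes but 2 of 6 cartilage genes. Scgb3a1, Scgb3a2, Foxj1 and Muc5b of this set also belong to the first airway and thyroid list, where they were not tested. Scgb3a2 was at 65.1 CPM and Foxj1 at 9.44 CPM in wild type replicate 3. How the tissue entered was not tested, and no biological explanation was tested.

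Chil4 in wild type was lowest in wild type replicate 3, with a ratio of 0.869 (159.4 against 183.9 to 187.6 CPM). The same library was lowest for Plk1, with 0.898. Wild type replicate 4 was highest for Mmp10, with 1 (1 count against 0), for Icos, with 0.87, and for Itgax, with 0.886. It was lowest for Serpinb13, with 0.847, and for Hrnr, with 0.856. Oas1a gave 0.957 for a low value of 1.01 CPM in wild type replicate 2 and 0.888 for a high value of 10.3 CPM in EoE33 replicate 4. Il23a gave 0.963 for 0 counts in wild type replicate 1.

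Among EoE33 libraries, replicate 2 was highest for Ighm, with 0.841 (3698 against 1396 to 1761 CPM), for Alox15, with 0.929 (3845 against 1959 to 2093 CPM), and for Cyp2b19, with 1 (1 count against 0). It was lowest for Tek, with 0.957. Replicate 3 was lowest for Il12a, with 0.939, and highest for Il4, with 0.926 (1.64 against 0.85 to 0.91 CPM). Replicate 1 was lowest for Il5, with 0.846, and Postn, with 0.847 (218.6 against 305.6 to 321.3 CPM). Replicate 4 was highest for Cox6a2, with 0.834.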

How the results depend on the processing

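Leaving out wild type replicates 1 and 3, leaving out the counts of Chil4 and adding Il36a to its list were chosen after the results were seen; all other settings were fixed before. No gene called in the main fit was called in the opposite direction under any setting. Bpifb1, lower but not called in the main fit, was called higher without wild type replicate 3 (edgeR adjusted p = 0.00139). It was also called higher without wild type replicates 1 and 3 (edgeR adjusted p = 0.00296). Scaling, filter and tool moved the numbers of genes by less than 1.5 times: 4948 to 5690 were higher and 5087 to 5705 lower with DESeq2 size factors, upper-quartile scaling, library size only, the DESeq2 test, limma-voom, robust = FALSE, other filters or the first surrogate variable. At an adjusted p of 0.01 the numbers were 4151 and 4137. With an absolute log2 fold change of at least 1 they were 2057 and 2496. Leaving out 1 library in turn gave 4825 to 5160 higher and 4880 to 5333 lower, and 1.42 to 1.66 for Il33. Without the counts of Chil4 and with library size only, 6081 were higher and 4538 lower, so the balance of rises and falls depended on scaling.

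The skeletal muscle term left 3 genes higher and 0 lower, with 1.574 for Il33 (edgeR adjusted p = 0.921), because the term nearly equals genotype: 0.885 to 1.048 in wild type and −1.217 to −0.666 in EoE33. Signs turned for Tnfrsf17 (−0.402), Mzb1 (−2.765), Ighm (−0.438), Mmp14 (−0.344), Tgfb1 (−0.055), Fbln2 (0.284), Crnn (−1.393), Zbtb16 (0.782), Atf3 (−1.347), Il4 (0.79), Il1rl1 (−2.546), Tslp (−2.37), Ccl24 (−3.407) and Postn (0.306), none of them called. List directions turned for B cell and plasma cell markers (camera adjusted p = 0.0029), fibroblast markers (0.563) and genes lowered in the human disease (0.299), and 16 lists were higher and 3 lower.

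The number of list calls was 0 higher and 0 lower with an estimated correlation between genes. It was 19 and 7 with fry, which tests another hypothesis, and 17 and 6 without a low-count filter. Called by fry but not by camera were the mast cell, T cell, B cell, adipocyte and interferon lists. The type 1 and type 17 list and the genes lowered in the human disease were too. With Il36a added the number of camera calls stayed at 14 and 5. The direction of the cornified envelope list turned with DESeq2 size factors (adjusted p = 0.978) and without a low-count filter (0.978). Its adjusted p lay between 0.578 and 0.991 with 1 library left out and was 0.49 without wild type replicates 1 and 3. For the extracellular matrix list the values were 0.689 to 0.994 and 0.803, also with turned directions.

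With 1 library left out, log2 fold changes crossed 0 for Il4 (−0.347 to 0.035), Il5 (−0.178 to 0.162), Tslp (−0.063 to 0.317), Postn (−0.132 to 0.079), Bpifa1 (−7.501 to 0.508) and Bpifb1 (−2.976 to 3.446). Without wild type replicates 1 and 3 they were 0.578 for Bpifa1, 4.192 for Bpifb1 and −0.103 for Tslp. Without the counts of Chil4 they were 0.047 for Il4, 0.069 for Il5 and 0.065 for Postn. With limma-voom Bpifb1 had 1.352.

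With a replicate block 4936 genes were higher and 5120 lower, with 16 lists higher and 6 lower, and Bpifb1 had 0.577. Correlations of libraries sharing a number were 0.104, −0.122, 0.056 and −0.136, against up to 0.152 with another number, so the numbers are not read as pairs.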

Other observations

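The tests of Chil4 against single libraries and against the IL-13 and IL-4 list were chosen after the values were seen, as were those of muscle dilution and of Chil4 counts; those of shared sequence, of further muscle genes and of other splits were written before. Within the lists, keratins and cytokines of wounded epithelium not named above were among the larger rises: Krt16 and Krt6b had log2 fold changes of 7.84 and 6.89, and Il24 8.23. Of the suprabasal genes, Krt1, Krt10 and Lor had −7.20, −3.77 and −3.92, and Krt1 was at 1.1 CPM in wild type replicate 3 against 122.5 to 277.1 CPM in the other 3, whereas Sprr2h and Sprr2b had 7.26 and 5.19. Il6 and Tnf had 6.81 and 3.84, and Pdcd1lg2, which encodes a ligand of PD-1, had 6.16. Wild type means were 0.011 CPM for Il6, 0.022 for Pdcd1lg2 and 0.064 for Il24, against 1.83, 1.96 and 21 in EoE33. These ratios rest on few wild type counts. The members given log2 fold changes in this paragraph were picked after their values were seen, and all passed the edgeR threshold.

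Skeletal muscle transcripts were lower in all 4 EoE33 libraries. Dilution of all other tissue by epithelium and immune cells would lower muscle and fibroblast genes alike, but muscle fell by a further 1.18 on the log2 scale (−1.183 in EoE33 minus wild type, standard error 0.13, exact permutation p = 0.0286, the smallest possible). Against smooth muscle the difference was −0.92 (exact p = 0.0571) and against adipocyte markers −0.24 (exact p = 0.686). It was −2.31 against endothelial and vessel genes and −0.96 against nerve markers (exact p = 0.0286 each). Of the 21 endothelial and vessel genes 7 rose, Sele and Icam1 among them, and 7 fell. The smooth muscle and nerve lists hold Des, Synm and Nos1, which skeletal muscle also expresses. These gaps therefore do not measure amounts of tissue alone. The gap to adipocyte markers had a standard error of 0.61, too wide to show whether they fell as far as muscle. Their mean levels overlapped between the groups. Wild type replicate 3 was at 4.8, and EoE33 replicates 1 and 4 were at 4.92 and 4.96 (log2 CPM). The test against fibroblast genes restates a gap already seen between the lists. It speaks only against an equal dilution of muscle and fibroblasts. Chil4 held a mean of 8.21% of the EoE33 counts, too small a share to lower the muscle genes this far. Leaving its counts out could therefore move the muscle median only slightly, and the resulting −1.861 was no independent test. Less skeletal muscle in the EoE33 tissue may account for the pattern. All 30 genes of a further muscle list fell, with a median of −1.859 against −1.961 for the first. Any cause that lowers muscle transcripts together gives this fall, so the further list cannot tell such causes apart. Lower transcription in each fibre, a difference in dissection and an effect of genotype on muscle remain open and untested.

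The rise of Chil4 took up more counts than any other change described here. Reads shared with a paralog are argued against, since 0% of the 1390 windows of 150 bases in its longest transcript occur in transcripts of another gene, Chil3 included. Dependence on a single library is argued against by a log2 fold change of at least 8.672 with any library left out. As a hypothesis, the rise may be part of the IL-13 and IL-4 response: 17 of the 20 other members of that list, Chil3 also set aside, were higher. Of all 16760 genes tested, 5238 were higher. The count of members restates the list result given above and does not link Chil4 to these cytokines. Whether IL-13 is needed was not tested, since no mice lacking it were analysed here.

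Among the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 10621 genes. The highest other split gave 0 by edgeR. A share of 1 in 35 is the smallest this test can give, so it speaks against chance only that far. Every other split mixed the groups, which puts the genotype difference into the spread within each set of 4, so the 0 does not measure false calls. For gene lists chance was not excluded by this test: 6 of 35 splits gave at least the 19 lists of the real split, and the highest other gave 22. The 5 others each parted the groups 3 to 1, so they hold part of the genotype difference.

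Liver transcripts were highest in wild type replicate 1 for 14 of 16 further liver genes, with Alb at 91.3 CPM and Apoa1 at 23.1 CPM against 0.3 to 1.35 in the other wild type libraries. Hp and Trf, which other tissues also express, were the 2 highest in wild type replicate 4.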
